A study of Mus musculus with 42 samples.

How the data were processed

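RNA of mouse CD4+ T cells was measured on 42 arrays read in 1 channel, each with cDNA of 1 sample labelled with 33P-dCTP, per the labels' protocols. The deposited values were spot intensities on a linear scale, 9600 per array, with no background column, no detection call and no negative value. The image reader, any background subtraction and any normalization behind these intensities are not given in the sources used here, so the brightness at which a spot saturates and the signal of an empty spot are unknown. The array medians of intensity ran from 5.74 to 12.99 and the 99th percentiles from 372.6 to 1909.8, and between 26 and 378 spots of an array were at 0. The deposited series matrix held the same intensities, each array multiplied by 1 constant (16 distinct constants to 4 digits). Arrays a and b of a sample had the same constant, and some samples of different groups shared one, such as 0.0886 for naive 3 and rested Th1 3. Its column medians ran from 0.936 to 1.151 and were 1 on 18 arrays, its scale was linear without centring of genes, and 9 of its cells were empty. It served as an alternative source of values.

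The platform table listed 3798 of the 4992 reporters. Each of 4608 reporters was spotted at 2 positions that lay 4992 positions apart, and 384 reporters stood once. The level of a spot and of its partner at that spacing correlated at r = 0.994 across spots, against 0.31 at the next best spacing, and the 3798 named pairs carried the same accession at both positions. A single gene was named for 3626 reporters and several genes for 172, while 1194 reporters are unnamed here. No gene was named from a reporter with several. Symbols were updated through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which held 3605 of the 3626 single-gene reporters, and 3230 distinct genes resulted. No genome build is given for the arrays in the sources used here, so no coordinates are printed.

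The 42 arrays belonged to 21 samples in 7 groups of 3, with arrays a and b for each sample. All arrays were quantile-normalised together on the linear scale, 1 was added, log2 was taken, the spots of a reporter were averaged, and then arrays a and b. Fold changes are therefore on the log2(intensity + 1) scale, which understates the change of dim genes. A linear model was fitted per reporter over all 7 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared 1 estimate of the spread, and contrasts of group means were adjusted by the Benjamini-Hochberg method over the 4992 reporters of each comparison. A reporter was called at a false discovery rate of 0.05. Every adjusted p of a gene comes from that limma fit, unless another fit is named beside it. There were 11 comparisons of 2 groups, the difference between lineages averaged over 3 stages, and 2 interactions that ask whether the rest step or the memory step differs between Th1 and Th2 cells. Table handling used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.

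The groups, the tests, most alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. By that rule the 8 largest rises and 8 largest falls of each of the 11 comparisons were taken among called single-gene reporters for which all 3 samples of 1 group lay beyond all 3 of the other, a separation that chance gives 10% of the time. For a gene with several reporters the brightest stood for the gene. The lineage mean used the same rule with all 3 stages differing in the same direction, and any member of the fixed lists could be named as well. Within this rule the genes printed were chosen mostly after their stability had been seen: of 156 results named by the rule, 126 kept their call in every fit without 1 sample and 30 lost it in at least 1. Over all 453 results of named genes and called list members, 312 kept it in every such fit and 141 did not.

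There were 21 lists, of which 15 had at least 5 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, against the 3230 genes. The 165 tests were adjusted together. These lists covered Th1-associated genes, Th2-associated genes, genes of naive and quiescent cells, T cell activation, the cell cycle, ribosomal proteins, glycolysis, oxidative phosphorylation, the proteasome, chaperones, interferon-induced genes, apoptosis, memory-associated genes, myeloid cell markers, and fibroblast and stromal markers. For B cell, granulocyte, erythroid and platelet, CD8 T and NK cell and thymocyte markers and for CD4 T cell genes, too few members were measured and only counts are given. Called tests numbered 45, and 17 of them held when camera estimated the correlation between genes, 38 by fry, which asks whether the genes of a list move 1 way on balance and makes no comparison with other genes, and 39 with the replicate block. By fry 62 of the 165 tests passed, and those that camera did not call are given for some lists only. Where a p is given as "with an estimated correlation", it is the adjusted p of camera in that form.

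The labels number the samples of each group from 1 to 3, and say nothing of what the number stands for. Deviations from the group means were correlated between same-numbered samples of the groups compared, and all 33 such correlations lay above 0.1, from 0.139 to 0.909. Over all groups, samples of other numbers gave -0.664 to 0.23 (median -0.222), with 11 of 126 above 0.1. Same-numbered pairs gave 0.546 to 0.909 in the 13 that share a spot pattern, described below, and 0.076 to 0.676 in the other 50. The numbers thus pair the samples in these data, though the lowest correlations overlap those of other numbers. The pairing comes from the data and not from a statement in the labels. All named genes and list members called without the block were also called with the replicate block, in which the sample number entered the fit as a fixed term, while 39 of the 45 list calls held. The blocked count is printed beside each result it moves by over 1.5 times.

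The ratio of array a to array b was the same to within 0.005 log2 at 100.0% of spots with an intensity of at least 3 in 13 of the 210 pairs of samples, while no other pair reached more than 1.46% of spots. These 13 pairs joined samples of different groups and the same number: the effector Th1 and Th2 samples of each number, the rested Th1 and Th2 samples of each number, naive and both memory samples numbered 1, the same numbered 3, and the memory samples numbered 2. They left 10 distinct patterns over the 21 samples. In such a pair the ratio between the samples was the same on both arrays and at both spots of a reporter, so arrays and spots gave 1 measurement of the difference and not several. No 2 arrays were identical. Nothing in the labels says that the samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

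Alternatives were all 42 arrays with the sample as a random block, only the a or only the b arrays, the replicate block, median centring or cyclic loess in place of quantile normalization, the series matrix values, the brighter 50% of the reporters, a larger offset of 1.67, a trended and robust variance model, array weights, a fit of only the groups compared, and each sample left out in turn. The pattern shared between samples as a random block, the naive and memory samples numbered 2 left out, and the list tests without each sample were added after seeing the data. The fit was tested on simulated values for effector Th1 against naive cells over 4992 reporters with 200 changed: 0 of 67 changes of 0.5 log2, 9 of 67 of 1 log2 (13.4%) and 55 of 66 of 2 log2 (83.3%) were called, with 2 unchanged reporters called. In this simulation of the fit without the block most changes of 1 log2 were missed. Precision is limited by the 3 samples per group, and other numbers of samples were not simulated.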

Results

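Gene expression was measured along the path from naive CD4+ T cells to Th1 and Th2 effector and memory cells of the mouse, with the title of the series naming the generation and purification of these cells as its subject. Naive cells came from the spleen of mice transgenic for GFP and for the AND T cell receptor, which recognises a pigeon cytochrome C peptide presented by I-Ek, and were low in CD44, high in CD62L and CD45RB and negative for CD25; the source field of the same labels names the thymus. Effector cells were harvested after 4 days of stimulation with antigen-presenting cells under Th1 or Th2 conditions. Rested cells had spent a further 3 days without antigen-presenting cells. Memory cells were rested cells transferred into thymectomised, irradiated and bone marrow-reconstituted mice and sorted 4 to 12 weeks later. The descriptions of the memory Th2 samples read RM-Th2 where their titles read M-Th2, and the titles were followed. Each of the 7 groups (naive, and effector, rested and memory cells of either lineage) held 3 samples with 2 arrays each, and all groups used 5 to 15 µg of total RNA from cryopreserved cells. Changes are given on the log2(intensity + 1) scale with their standard error (SE), for 3 samples per group. The SE comes from the spread shared by all 7 groups in the fit, not from the compared groups alone. It may thus be too small where those groups scatter more.

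Samples of a group correlated at r = 0.893 to 0.974 across reporters. The median SD of a reporter within a group was lowest in effector Th2 cells (0.27) and highest in memory Th1 cells (0.46), with memory Th2 cells at 0.44 and rested Th1 cells at 0.41. The first 3 principal components held 25.4%, 22.8% and 12.2% of the variance. Effector samples of both lineages lay at the high end of the first component, from 21.28 to 41.15, and no sample of another group lay above 1.08 there. In 13 pairs of samples from different groups and with the same number, the spot-to-spot pattern of array a against array b was identical, so that the 42 arrays carried 10 such patterns. These pairs took in all 3 numbers in each comparison of Th1 with Th2 cells of 1 stage, and numbers 1 and 3 in the comparisons of memory with naive cells. No pattern was shared between naive and effector, effector and rested, or rested and memory cells. In those steps a change of stage cannot be told apart from a change of pattern, and the larger counts below fall in them. With the pattern as a random block, memory Th1 against naive cells had 1489 calls and effector Th1 against naive cells 485.

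**Figure D1:**
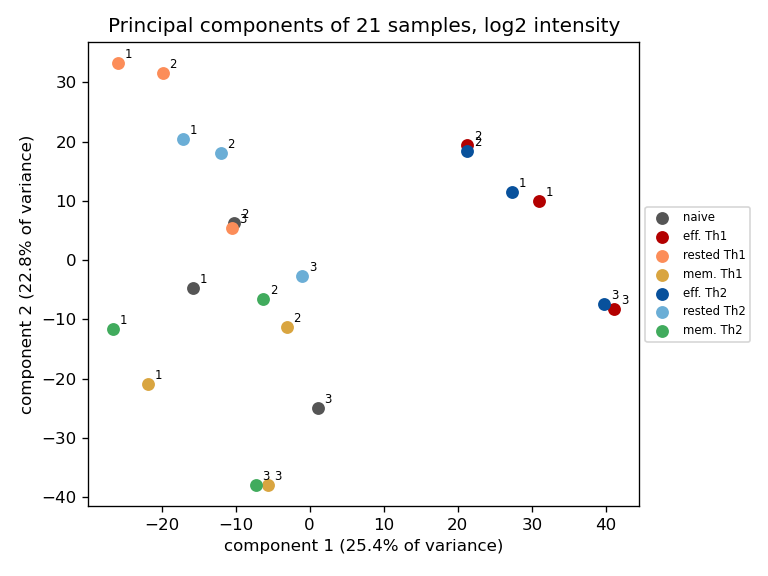
Each point is 1 of 21 samples, labelled by its number and coloured by group, on the first (25.4% of variance) and second (22.8%) principal components of log2 intensity. Effector samples lie at the right, from 21.28 to 41.15, and samples numbered 3 lie lowest on the second component in every group.

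Effector Th1 cells were compared with naive cells to show what stimulation under Th1 conditions changed. Genes of glycolytic enzymes were among the largest rises. Pgk1 (Entrez 18655), which encodes phosphoglycerate kinase, rose by 5.12 ± 0.43 (SE, n = 3 per group; 34.9-fold, adjusted p = 5.56e-08), the aldolase gene Aldoa by 4.45 ± 0.35 and the pyruvate kinase gene Pkm by 3.98 ± 0.24. The prion protein gene Prnp (Entrez 19122) rose by 5.26 ± 0.32 (38.3-fold). Ifitm3 (Entrez 66141), an interferon-induced antiviral membrane protein, rose by 4.78 ± 0.30 and Ero1a, the oxidase of disulfide formation in the endoplasmic reticulum, by 4.06 ± 0.25. The MAP kinase phosphatase gene Dusp10 fell by 3.99 ± 0.37 and Rgs2, a regulator of G protein signalling, by 3.20 ± 0.35. Tsc22d3, a glucocorticoid-induced gene of resting lymphocytes, fell by 2.61 ± 0.28 (adjusted p = 1.29e-06), and Nfkbia, the inhibitor of NF-κB, by 2.53 ± 0.23.

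By list in effector Th1 against naive cells, 6 of 9 measured glycolysis genes rose and none fell (7 adjusted over the list alone; list adjusted p = 1.59e-10). Of 36 cell cycle genes 17 rose and 0 fell (19 adjusted over the list alone; adjusted p = 1.59e-10), among them the mitotic cyclin gene Ccnb2 (3.60 ± 0.33), Top2a, which untangles DNA (3.21 ± 0.24), and Cdk1 (2.75 ± 0.25). Of 38 genes of oxidative phosphorylation 10 rose, or 13 adjusted over the list alone and 17 with the replicate block, with the complex I subunit gene Ndufv3 at 2.61 ± 0.26. The list call (adjusted p = 5.63e-07) was lost with an estimated correlation (adjusted p = 0.384), but not where the replicate block was added to that test (adjusted p = 0.0371). Of 11 myeloid cell markers 4 fell and none rose (1 rose and 4 fell adjusted over the list alone; 1 rose with the replicate block; adjusted p = 0.00364), including the lysozyme gene Lyz2, by 3.33 ± 0.31, and the Fc receptor chain gene Fcer1g, by 1.74 ± 0.34. The myeloid call held with an estimated correlation (adjusted p = 0.0352), but not with the replicate block added (adjusted p = 0.0596). The granulocyte marker S100a9 fell by 3.73 ± 0.33 alongside them. In effector Th1 cells S100a9 stood at 1.57 and Lyz2 at 2.84, both under the median reporter (3.13), so the size of these 2 falls rests partly on dim values. Among Th1-associated genes Gzmb, the cytotoxic protease granzyme B, rose by 3.60 ± 0.46. The interleukin 12 receptor gene Il12rb1 was called too (1.38 ± 0.36, adjusted p = 0.0156), but not without naive 2 (0.0896), effector Th1 1 (0.113) or effector Th1 3 (0.0706). With 2 of 6 called, also adjusted over the list alone, the Th1-associated list did not pass by camera (adjusted p = 0.126). By fry it was higher (adjusted p = 0.0187), as it was in effector Th2 against naive cells (0.00728). Of 30 proteasome genes 5 rose, also adjusted over the list alone (7 rose and 1 fell with the replicate block). The list passed with the block (adjusted p = 0.065, and 0.0498 with the block) or with median centring (0.00539), but not with an estimated correlation.

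In all, 276 reporters rose and 217 fell in effector Th1 against naive cells (493; 1010 at unadjusted p under 0.05). With the replicate block 836 were called. With median centring of the arrays the median change of all reporters was -0.13 in this comparison and -0.10 in the next, against -0.05 and -0.06 with quantile normalization.

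Effector Th2 cells were compared with the same naive cells. Pgk1 rose by 4.94 ± 0.43 (SE, n = 3 per group; 30.6-fold), Pkm by 3.78 ± 0.24 and Lgals1, which encodes galectin-1, by 4.05 ± 0.21 (adjusted p = 1.26e-10). The granzyme genes rose, Gzmb by 4.32 ± 0.46 and Gzma by 3.72 ± 0.26. Rnf128, a ubiquitin ligase linked to T cell anergy, rose by 4.70 ± 0.35 and the myosin gene Myo6 by 4.12 ± 0.37. S100a9 fell by 3.76 ± 0.33, Lyz2 by 3.18 ± 0.31, the actin cross-linker gene Actn1 by 3.22 ± 0.30, Tsc22d3 by 2.57 ± 0.28, and Smad4, the shared transducer of TGF-β signals, by 2.30 ± 0.31. In effector Th2 cells S100a9 stood at 1.55 and Lyz2 at 2.99, both under the median reporter (3.13), so the size of these 2 falls rests partly on dim values.

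Of 9 glycolysis genes 6 rose in effector Th2 cells, also adjusted over the list alone, and of 36 cell cycle genes 17 rose (20 adjusted over the list alone), with an adjusted p of 4.62e-10 for either list. Of 38 oxidative phosphorylation genes 11 rose (16 adjusted over the list alone, 21 with the replicate block; adjusted p = 5.67e-10, and 0.247 as the adjusted p with an estimated correlation, or 0.0121 with the block added to that). Of 13 memory-associated genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0164). That call was lost with an estimated correlation (adjusted p = 0.14) and with the replicate block (adjusted p = 0.0501). Its members that rose included Lgals1, Gzma, the calcium-binding membrane protein gene Anxa2 (2.42 ± 0.39) and Crip1 (2.33 ± 0.39), while Gimap4, a GTPase of lymphocytes, fell by 1.29 ± 0.22. Of 14 genes of naive and quiescent cells 2 fell and none rose (3 fell adjusted over the list alone; 1 rose and 3 fell with the replicate block), Tsc22d3 and the antiproliferative gene Btg1 (by 1.58 ± 0.32). This list was called at an adjusted p of 0.0402, but not with an estimated correlation (adjusted p = 0.31), with the replicate block (adjusted p = 0.0521), without naive 3 (0.0858) or without effector Th2 2 (0.071). Myeloid markers fell for 3 of 11 genes, also adjusted over the list alone (adjusted p = 0.00241), with Fcer1g falling by 1.73 ± 0.34. Of 3 thymocyte markers 1 fell (2 adjusted over the list alone), the CD1d gene Cd1d1 by 1.83 ± 0.31.

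The totals for effector Th2 against naive cells were 265 rises and 191 falls (456; 949 at unadjusted p under 0.05), and 761 calls with the replicate block. Both effector groups were set against the same 3 naive samples, which cannot be split. Reporters higher in both numbered 219, those lower in both 169 and those opposite 0, against 14.7 and 8.3 for independent lists of these lengths and at most 1 in 20 simulations of unchanged groups against the shared samples. Effector samples of the same number also deviated together across the lineages (r = 0.788, 0.909 and 0.879) and shared their spot patterns. With noise shared in that way, a test chosen after the data were seen, 20 simulations again gave at most 1. These simulations hold no real effects, and part of the excess may come from the shared naive samples and from this pairing.

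Rested Th1 cells were compared with effector Th1 cells to show what 3 days without antigen-presenting cells changed. Ifitm3 fell by 5.43 ± 0.30 (SE, n = 3 per group; 43.3-fold, adjusted p = 5.97e-10), the protein cross-linking enzyme gene Tgm2 by 4.68 ± 0.31, Pgk1 by 4.52 ± 0.43, Gzmb by 3.89 ± 0.46 and Top2a by 3.62 ± 0.24. Large rises included those of Xpo4, a nuclear export receptor (4.62 ± 0.83), Shisal1 (4.14 ± 0.33), the potassium channel gene Kcnj12 (3.76 ± 0.46) and the anion exchanger gene Slc4a2 (3.47 ± 0.24). Of 36 cell cycle genes 19 fell (25 adjusted over the list alone; adjusted p = 3.89e-11), with Gmnn, the inhibitor of DNA replication licensing, falling by 2.93 ± 0.23. Of 9 glycolysis genes 6 fell, also adjusted over the list alone (adjusted p = 3.36e-06).

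Of 15 chaperone genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; 11 fell with the replicate block; adjusted p = 0.00191), including Hsp90b1 of the endoplasmic reticulum (by 2.03 ± 0.20) and the cytosolic Hspa8 (by 2.01 ± 0.44). The chaperone call held with an estimated correlation (adjusted p = 0.0451), but not with the replicate block added (adjusted p = 0.112). Of 30 proteasome genes 6 fell (10 fell and 1 rose adjusted over the list alone; 12 fell and 1 rose with the replicate block), with the catalytic-core subunit gene Psmb2 falling by 1.79 ± 0.25, and of 38 oxidative phosphorylation genes 10 fell (11 adjusted over the list alone), with the cytochrome c gene Cycs falling by 2.34 ± 0.24. Their adjusted p values of 0.00123 and 0.000108 became 0.489 and 0.496 as adjusted p with an estimated correlation. Of 6 T cell activation genes 2 fell, also adjusted over the list alone, the co-stimulatory receptor gene Tnfrsf9 (by 1.80 ± 0.34) and the early-response gene Egr1 (by 1.24 ± 0.22), and the list did not pass (adjusted p = 0.179). Of 9 apoptosis genes 2 fell (2 adjusted over the list alone, 4 with the replicate block; adjusted p = 0.103), with the caspase gene Casp6 at a fall of 2.63 ± 0.38. Of 34 ribosomal protein genes 5 rose and 5 fell, also adjusted over the list alone (8 and 6 with the replicate block; adjusted p = 0.442). Among myeloid markers 2 of 11 rose, also adjusted over the list alone, the lysosomal protease genes Lgmn (1.73 ± 0.27) and Ctsb (1.62 ± 0.27). That list call (adjusted p = 0.0335) was lost with an estimated correlation (adjusted p = 0.118) and without rested Th1 3 (0.0609). Of 11 fibroblast and stromal markers 1 rose and 1 fell (1 and 2 adjusted over the list alone; 2 and 2 with the replicate block; adjusted p = 0.662), and the fibronectin gene Fn1, the member that fell, did so by 2.92 ± 0.32. Of 4 granulocyte markers 1 rose and 1 fell, also adjusted over the list alone, with the G-CSF receptor gene Csf3r rising by 1.85 ± 0.42. Of 4 erythroid and platelet markers 1 rose (2 adjusted over the list alone), the integrin gene Itga2b by 0.90 ± 0.23.

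Rested Th1 cells had 380 rises and 430 falls against effector Th1 cells (810; 1420 at unadjusted p under 0.05), or 285 and 474 with median centring. With the replicate block 1362 reporters were called, and without effector Th1 3 the count was 522.

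In rested against effector Th2 cells Gzmb fell by 4.55 ± 0.46 (SE, n = 3 per group; 23.5-fold, adjusted p = 1.98e-06) and Gzma by 4.30 ± 0.26. Pgk1 fell by 3.92 ± 0.43, Myo6 by 3.79 ± 0.37, Ccnb2 by 3.47 ± 0.33 and Pkm by 3.11 ± 0.24. Among rises, the selenium transport protein gene Selenop rose by 2.91 ± 0.39, Actn1 by 2.46 ± 0.30, the netrin receptor gene Unc5b by 2.34 ± 0.31, Shisal1 by 2.27 ± 0.33 and Fndc3a by 2.11 ± 0.29. Of 36 cell cycle genes 17 fell (21 adjusted over the list alone; adjusted p = 6.8e-15) and of 9 glycolysis genes 6 fell, also adjusted over the list alone (adjusted p = 2e-08). Of 38 oxidative phosphorylation genes 3 fell, also adjusted over the list alone (13 with the replicate block; adjusted p = 7.47e-05, and 0.496 as the adjusted p with an estimated correlation). Of 15 chaperone genes 1 fell, Hsp90b1 by 1.54 ± 0.20 (5 fell and 1 rose adjusted over the list alone; 6 fell and 1 rose with the replicate block). The chaperone call (adjusted p = 0.00636) was lost with an estimated correlation (adjusted p = 0.0838).

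Of 6 measured Th1-associated genes 2 fell in rested Th2 cells, also adjusted over the list alone: Gzmb and Il12rb1, the latter by 2.46 ± 0.36. This list call (adjusted p = 0.0372) was lost with an estimated correlation (adjusted p = 0.369), with the replicate block (adjusted p = 0.0726), with median centring (adjusted p = 0.0505) and without rested Th2 1 (0.0719). Of 30 proteasome genes 3 fell (4 adjusted over the list alone, 5 with the replicate block; adjusted p = 0.00763, and 0.61 as the adjusted p with an estimated correlation), and the list was not called by fry (0.0633) or without effector Th2 3 (0.0517). Among myeloid markers 1 of 11 rose (2 adjusted over the list alone, 3 with the replicate block), Ctsb by 1.34 ± 0.27. The list call (adjusted p = 0.0359) was lost with an estimated correlation (adjusted p = 0.121) and without effector Th2 2 (0.0615), effector Th2 3 (0.0585), rested Th2 1 (0.0514) or rested Th2 3 (0.0654). In rested Th2 cells 172 reporters rose and 206 fell (378; 937 at unadjusted p under 0.05), or 104 and 213 with median centring. With the replicate block 790 were called, and the count was 242 without effector Th2 1, 214 without effector Th2 3 and 236 without rested Th2 1.

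Memory Th1 cells, recovered from mice weeks after transfer, were compared with rested Th1 cells, the stage at which cells were transferred. Whether the rested samples were the very preparations transferred is not known here. Gzma fell by 4.88 ± 0.26 (SE, n = 3 per group; 29.5-fold, adjusted p = 4.71e-10), and falls were also called for Blzf1, by 4.38 ± 0.46, Xpo4, by 4.04 ± 0.83, Fndc3a, by 3.66 ± 0.29, and Shisal1, by 3.48 ± 0.33. Gzma lay under the median reporter (3.13) in memory Th1 cells, so the size of its fall rests on dim values. Itgb2, the β chain of the leukocyte integrins, fell by 3.96 ± 0.59. Vps37b, of the ESCRT sorting machinery, rose by 2.76 ± 0.38 (adjusted p = 7.65e-05), Ifrd1 by 2.51 ± 0.33, the Hsp40 co-chaperone gene Dnaja1 by 2.43 ± 0.25, Tsc22d3 by 2.15 ± 0.28 and the anti-apoptotic gene Bcl2a1d by 2.07 ± 0.35.

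Of 30 proteasome genes 7 rose and 1 fell in memory Th1 cells, also adjusted over the list alone (12 rose with the replicate block; adjusted p = 0.00656, and 0.593 as the adjusted p with an estimated correlation), with Psmb2 at 1.52 ± 0.25. Of 15 chaperone genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; 7 and 1 with the replicate block; adjusted p = 0.0107, and 0.117 as the adjusted p with an estimated correlation), with Hspa8 at 2.00 ± 0.44. The mitochondrial Hspe1 rose by 1.63 ± 0.30, while the chaperonin subunit gene Cct4 fell by 1.61 ± 0.36. Of 38 oxidative phosphorylation genes 5 rose (4 adjusted over the list alone, and 12 rose and 1 fell with the replicate block). That list passed with the block (adjusted p = 0.0652, and 0.0484 with the block) or with median centring (0.00208), but not with an estimated correlation. Of 34 ribosomal protein genes 6 rose (6 rose and 1 fell adjusted over the list alone; 10 and 2 with the replicate block), with Rpl7 at 1.81 ± 0.42. The ribosomal call (adjusted p = 0.0148) was lost with an estimated correlation (adjusted p = 0.327) and without memory Th1 2 (0.0615). Of 13 memory-associated genes 2 fell and 1 rose, also adjusted over the list alone (4 and 2 with the replicate block). Those that fell were Gzma, a cytotoxic protease, and Itgb2, a chain of the leukocyte integrins. The call (adjusted p = 0.0499) was lost with an estimated correlation (adjusted p = 0.229), with the replicate block (adjusted p = 0.0501), with median centring (adjusted p = 0.127) and without rested Th1 1 (0.0968), rested Th1 3 (0.0589) or memory Th1 1 (0.117).

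Some markers of other cell types moved with these groups. Among myeloid markers 3 of 11 fell in memory against rested Th1 cells (5 fell and 1 rose adjusted over the list alone; 4 fell and 1 rose with the replicate block), among them Lyz2, by 2.15 ± 0.31, and Lgmn, by 1.83 ± 0.27. The myeloid call (adjusted p = 0.0335) was lost with an estimated correlation (adjusted p = 0.118), with the replicate block (adjusted p = 0.0577) and without rested Th1 3 (0.0939) or memory Th1 2 (0.0951). Of 4 granulocyte markers 2 fell (3 fell and 1 rose adjusted over the list alone), S100a9 by 1.76 ± 0.33 and the lactoferrin gene Ltf by 1.18 ± 0.27. Memory Th1 cells held Lyz2 at 0.93 and S100a9 at 0.44, against a median reporter of 3.13. Of 4 erythroid and platelet markers 3 fell, also adjusted over the list alone, with Itga2b falling by 1.59 ± 0.23. Of 11 stromal markers 1 fell, also adjusted over the list alone (2 rose and 3 fell with the replicate block; adjusted p = 0.366), Sparc, a collagen-binding matrix protein, by 2.59 ± 0.36. In total 470 reporters rose and 417 fell (887; 1592 at unadjusted p under 0.05), or 576 and 337 with median centring, which put the median of all reporters at 0.11 in place of 0.09. With cyclic loess the balance turned, to 402 rises and 434 falls, as it did with only the groups compared (66 and 116, 182 in all). The b arrays alone gave 576 and array weights 547. With the replicate block 1607 were called, and the count was 579 without rested Th1 1 and 555 without memory Th1 3.

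In memory against rested Th2 cells Gzma fell by 3.81 ± 0.26 (SE, n = 3 per group; adjusted p = 3.58e-08) and granzyme D (Gzmd) by 2.62 ± 0.21. Gzma lay under the median reporter (3.13) in memory Th2 cells, so the size of its fall rests on dim values. Kcnj12 fell by 2.49 ± 0.46, Selenop by 2.45 ± 0.39, the lysosomal protease gene Ctsd by 2.34 ± 0.43 and Fndc3a by 2.14 ± 0.29. Rises included the CD1d gene Cd1d1 (2.64 ± 0.31), Ifrd1 (2.56 ± 0.33), Vps37b (2.42 ± 0.38), the interferon-γ-induced GTPase gene Igtp (2.27 ± 0.42), Bcl2a1d (2.15 ± 0.35), Tsc22d3 (2.11 ± 0.28) and the transcription factor gene Klf4 (2.06 ± 0.33). Of 13 memory-associated genes 2 fell (3 fell and 1 rose adjusted over the list alone; 6 and 1 with the replicate block; adjusted p = 0.0136, and 0.128 as the adjusted p with an estimated correlation), led by Gzma. Of 34 ribosomal protein genes 1 rose (1 adjusted over the list alone, 2 with the replicate block; adjusted p = 0.00241, and 0.206 as the adjusted p with an estimated correlation). Of 15 chaperone genes 2 rose, also adjusted over the list alone (4 rose and 1 fell with the replicate block). That list passed with the block (adjusted p = 0.0548, and 0.048 with the block), with median centring (0.0227) and by fry (0.00222), but not with an estimated correlation. Of 4 CD4 T cell genes 2 fell, also adjusted over the list alone, and 1 of them, the adaptor gene Skap1, did so by 1.85 ± 0.32, a call kept in every fit without 1 sample. The totals were 114 rises and 81 falls (195; 953 at unadjusted p under 0.05), with 719 called under the replicate block and 313 on 42 arrays. Fewer were called with median centring (103; 58 rises and 45 falls), on the b arrays alone (127) and with only the groups compared (46). The count was 109, 99 and 94 without rested Th2 1, 2 and 3, 305 without memory Th2 2 and 108 without memory Th2 3.

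Memory cells were also compared with naive cells, both of them taken from mice. In memory Th1 cells Lyz2 fell by 5.23 ± 0.31 (SE, n = 3 per group; 37.6-fold, adjusted p = 1.32e-09), Gzma by 5.02 ± 0.26, S100a9 by 4.87 ± 0.33, the atypical protein kinase C gene Prkci by 4.26 ± 0.33 and Fcer1g by 2.82 ± 0.34. There Lyz2 stood at 0.93 and S100a9 at 0.44, against a median reporter of 3.13, and Gzma also lay under that median. The size of these falls thus rests on dim values. Igsf10 rose by 2.23 ± 0.35 (adjusted p = 0.00171), the mitochondrial co-chaperone gene Dnajc15 by 2.12 ± 0.27 and Sugt1 by 1.38 ± 0.21, although its second reporter had the opposite sign. Of 11 myeloid markers 2 fell (5 adjusted over the list alone; adjusted p = 0.00191, with an estimated correlation adjusted p = 0.0322, and 0.0713 with the replicate block added), and of 4 granulocyte markers S100a9 and Ltf (by 1.63 ± 0.27), also adjusted over the list alone. Of 3 thymocyte markers 1 fell (2 adjusted over the list alone), Cd24a by 2.00 ± 0.37, a call lost without naive 1 (adjusted p = 0.0622). Of 38 oxidative phosphorylation genes 0 passed singly by limma (1 rose adjusted over the list alone; 7 rose and 1 fell with the replicate block), but the list was higher by camera (median 0.44; adjusted p = 0.00012, and 0.498 as the adjusted p with an estimated correlation), though not by fry (0.124). Of 34 ribosomal protein genes 0 passed singly (2 adjusted over the list alone, 3 with the replicate block) and the list was higher (adjusted p = 0.0136, and 0.322 as the adjusted p with an estimated correlation), but not without memory Th1 2 (0.139). The proteasome list passed with the replicate block (adjusted p = 0.0652, and 0.0414 with the block) and with median centring (0.00775), but not with an estimated correlation. Calls numbered 18 higher and 21 lower (39; 630 at unadjusted p under 0.05), or 26 and 15 with median centring, and 298 with the replicate block. With the shared spot pattern as a random block, a fit chosen after the data were seen, the count was 1489. It was 8 with only the groups compared, 18 and 21 on the a and b arrays alone, and 59 with cyclic loess. The count was 25, 15 and 14 without naive 1, 2 and 3, and 19, 94 and 24 without memory Th1 1, 2 and 3.

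In memory Th2 against naive cells Gzma fell by 4.39 ± 0.26 (SE, n = 3 per group; adjusted p = 3.25e-09), Lyz2 by 3.25 ± 0.31, Tulp4 by 2.98 ± 0.26, Fcer1g by 2.45 ± 0.34 and S100a9 by 2.11 ± 0.33. Here too the level of Gzma in memory Th2 cells lay under the median reporter (3.13), so the size of its fall rests on dim values. Myeloid markers fell for 2 of 11 genes, also adjusted over the list alone (adjusted p = 0.00191). That call held with an estimated correlation (adjusted p = 0.0322), but not with the replicate block added (adjusted p = 0.0687). Of 7 interferon-induced genes 0 passed singly by limma (1 adjusted over the list alone, 2 with the replicate block) while the list was higher by camera (median 0.32; adjusted p = 0.00673), with Igtp at 1.69 ± 0.42 (adjusted p = 0.118). This list was not called without memory Th2 2 (0.0503). Of 34 ribosomal protein genes 0 passed singly (1 adjusted over the list alone, 1 with the replicate block), and the list (adjusted p = 0.00718) was lost with an estimated correlation (adjusted p = 0.265) and without memory Th2 2 (0.0759). The oxidative phosphorylation list was higher (median 0.18, adjusted p = 0.0132), but not with an estimated correlation (adjusted p = 0.691), by fry (0.441) or without naive 2 (0.186), memory Th2 2 (0.074) or memory Th2 3 (0.126). Calls numbered 7 higher and 7 lower (14; 441 at unadjusted p under 0.05), or 3 and 5 with median centring and with cyclic loess, 70 with the replicate block and 1187 with the shared pattern as a random block. With only the groups compared 4 were called, and 6 on the b arrays alone. The count was 7, 6 and 7 without naive 1, 2 and 3, and 8, 33 and 7 without memory Th2 1, 2 and 3.

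**Figure D2:**
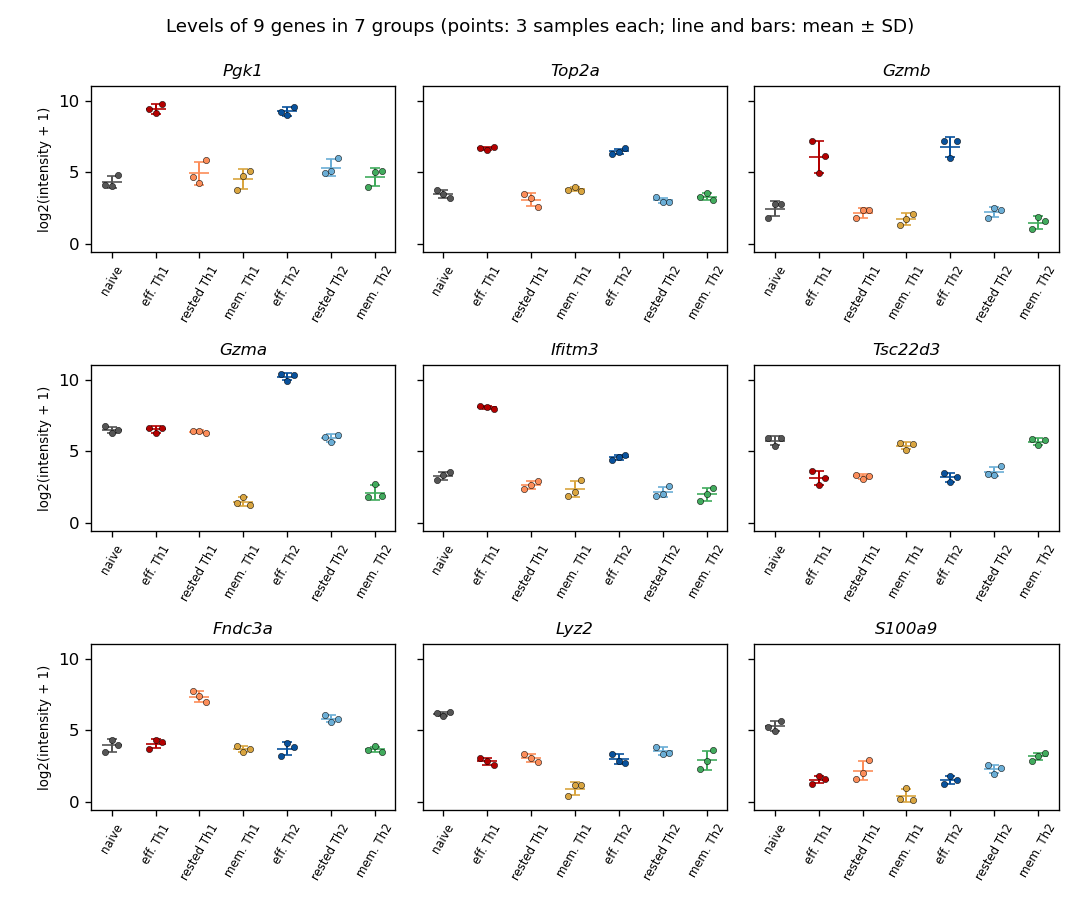
Points are the 3 samples of each of 7 groups, and the line and bars their mean and SD, on a log2(intensity + 1) axis, for 9 genes named by the rule. Pgk1, Top2a and Gzmb stand highest in both effector groups, Gzma is lowest in memory Th1 and memory Th2 cells, Tsc22d3 is lower in effector and rested than in naive cells, and Lyz2 and S100a9 stand highest in naive cells.

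Th1 and Th2 cells of the same stage were compared to show what the polarising conditions changed. In effector cells Ifitm3 was higher in Th1 by 3.50 ± 0.30 (SE, n = 3 per group; 11.3-fold, adjusted p = 7.65e-07), Prnp by 3.01 ± 0.32 and Tgm2 by 2.10 ± 0.31. Jun, a subunit of the AP-1 transcription factor, was higher by 2.46 ± 0.41 (adjusted p = 0.005), a call lost without effector Th1 2 (0.0555). Gzma was lower in Th1 than in Th2 effector cells (-3.70 ± 0.26, adjusted p = 7.22e-08), as were Myo6 (-3.68 ± 0.37) and Rnf128 (-2.67 ± 0.35). Of 7 interferon-induced genes in the list, which does not hold Ifitm3, 0 passed singly by limma (2 adjusted over the list alone, 1 with the replicate block), while the list was higher in Th1 by camera (median 0.46; adjusted p = 1.46e-08), with the MHC class I light chain gene B2m at 0.96 ± 0.21 (adjusted p = 0.0603) and Igtp at 1.35 ± 0.42 (adjusted p = 0.721).

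The lineage lists themselves showed little between the effectors. Of the 6 measured Th1-associated genes 0 passed by limma, and adjusted over the list alone 0 (list adjusted p = 0.376). Of 6 Th2-associated genes 0 passed either way (adjusted p = 0.581), with the Th2 cytokine gene Il13 at 2.36 in Th1 and 1.85 in Th2 effector cells. The genes for interferon-γ, interleukin 4, T-bet and GATA3 were not analysed here. Of 13 memory-associated genes 1 was lower in Th1, Gzma, also adjusted over the list alone. By camera that list was lower (adjusted p = 0.00118) although its median was 0.02 and its mean -0.35. With an estimated correlation the call held (adjusted p = 0.0442), but not with the replicate block added (adjusted p = 0.118). The glycolysis list, with 0 genes passing singly, was called as higher with the replicate block (adjusted p = 0.0549, and 0.0414 with the block), but not with an estimated correlation. The oxidative phosphorylation list was lower in Th1 effectors (median -0.09; adjusted p = 0.0333) with 0 genes passing singly. That call was lost with an estimated correlation (adjusted p = 0.716), by fry (0.712), with median centring (adjusted p = 0.0644) and without effector Th1 1 (0.111), effector Th1 2 (0.841) or effector Th2 3 (0.862). In all 9 reporters differed, 6 higher and 3 lower in Th1 (105 at unadjusted p under 0.05), and 26 with the replicate block. The count was 26 with array weights, and 121 (78 higher and 43 lower) with the shared spot pattern as a random block.

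Rested Th1 cells had 18 reporters higher than rested Th2 cells and 0 lower by limma (452 at unadjusted p under 0.05). Among the largest named differences were Blzf1 at 2.14 ± 0.46 (SE, n = 3 per group; adjusted p = 0.0448), Bbs7, a subunit of the ciliary BBSome, at 1.99 ± 0.36 and Shisal1 at 1.89 ± 0.33, and each call was lost without rested Th1 1 (adjusted p = 0.226, 0.122 and 0.109), rested Th2 2 (0.228, 0.147 and 0.147) and rested Th2 3 (0.399, 0.144 and 0.119). Kank2 stood higher by 1.90 ± 0.32 (adjusted p = 0.0126), a call lost without rested Th2 2 (0.147) or rested Th2 3 (0.103). With the replicate block 118 reporters were called, 75 higher and 43 lower, and with the shared spot pattern as a random block 1005, 449 higher and 556 lower. By limma 0 were called on the a arrays alone (352 at unadjusted p under 0.05) and 0 with only the groups compared (388). Median centring gave 7, the b arrays 9 and array weights 37. The count was 1 without rested Th1 1, 43 without rested Th1 3, and by limma 0 without rested Th2 2 (347 at unadjusted p under 0.05) and 0 without rested Th2 3 (262). Interferon-induced genes were higher in rested Th1 cells as a list (adjusted p = 0.00656; lost without rested Th1 3, 0.0939), with 1 of 7 called, also adjusted over the list alone. That gene was B2m at 1.03 ± 0.21 (adjusted p = 0.0278), lost without rested Th1 1 (0.148), rested Th1 2 (0.0635), rested Th2 2 (0.19) or rested Th2 3 (0.188) and with median centring (0.401; alternatives from 1.84e-06 to 0.401). The Th2-associated list was higher in Th1 cells (adjusted p = 0.0249), with 0 of 6 passing singly and 2 adjusted over the list alone (1 with the replicate block), the cytokine genes Il13 (1.43 ± 0.41) and Il24 (1.41 ± 0.39). It was lost with an estimated correlation (adjusted p = 0.225), by fry (0.0633) and without rested Th1 1 (0.0835), rested Th1 3 (0.123) or rested Th2 2 (0.0947). Chaperone genes (adjusted p = 0.0315) and oxidative phosphorylation genes (adjusted p = 0.00519) were lower as lists in Th1 cells, with 0 genes passing singly (2 chaperone genes adjusted over the list alone and with the replicate block, and 1 of the other list with the block). Both were lost with an estimated correlation (adjusted p = 0.178 and 0.648). The chaperone list was also lost with the replicate block (adjusted p = 0.0609) and without rested Th1 1 (0.0601), rested Th1 3 (0.0783) or rested Th2 2 (0.0521), and the oxidative phosphorylation list by fry (0.296) and without rested Th1 2 (0.198) or rested Th2 3 (0.119).

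In memory cells Prkci was lower in Th1 than in Th2 (-3.41 ± 0.33, SE, n = 3 per group; adjusted p = 1e-05), as was the granulocyte marker S100a9 (-2.75 ± 0.33, adjusted p = 0.000164). Lyz2 was also lower (-1.98 ± 0.31, adjusted p = 0.00487), a call lost without memory Th1 1 (0.0524), and Dnajc15 was higher (1.62 ± 0.27, adjusted p = 0.00931), lost without memory Th2 1 (0.0891). Memory Th1 cells held S100a9 at 0.44 and Lyz2 at 0.93, against a median reporter of 3.13, so the size of both differences rests on dim values. Among myeloid markers 1 of 11 was lower, also adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.133; 0.031 by fry). Of 4 granulocyte markers 2 were lower, also adjusted over the list alone, S100a9 and Ltf (-1.37 ± 0.27, adjusted p = 0.0396). The call of Ltf was lost without memory Th1 1 (0.321), memory Th1 3 (0.103), memory Th2 1 (0.166) or memory Th2 3 (0.202). The oxidative phosphorylation list was higher (median 0.14, adjusted p = 0.0283) with 0 genes passing singly, and was lost with an estimated correlation (adjusted p = 0.709), by fry (0.53) and without memory Th1 2 (0.125), memory Th1 3 (0.234), memory Th2 1 (0.361) or memory Th2 2 (0.0759). Calls numbered 2 higher and 8 lower (10; 199 at unadjusted p under 0.05), or 1 and 10 with cyclic loess, 20 with the replicate block and 396 with the shared pattern as a random block. By limma 0 were called with only the groups compared (92 at unadjusted p under 0.05), and 5 with array weights, on the a arrays alone or with a trended and robust variance. The count was 4 without memory Th1 1 and 6, 17 and 5 without memory Th2 1, 2 and 3.

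Averaged over the 3 stages, with 9 samples per lineage, 10 reporters were higher and 6 lower in Th1 (16; 246 at unadjusted p under 0.05), 37 were called with the replicate block and 514 with the shared pattern as a random block, but 7 and 10 on the a and b arrays alone. Ifitm3 was higher by 1.44 ± 0.17 (adjusted p = 0.000182), Jun by 1.34 ± 0.24, Prnp by 1.18 ± 0.19, Dnajc15 by 1.12 ± 0.16, the transcription factor gene Klf7 by 1.05 ± 0.20 and B2m by 0.65 ± 0.12. The call of B2m was lost with median centring (adjusted p = 0.0793; alternatives from 4e-07 to 0.0793). Gzma was lower (-1.30 ± 0.15), as was Myo6 (-1.60 ± 0.22). The means of Ifitm3, Prnp and Myo6 came largely from the effector stage. From effector to rested cells their Th1 minus Th2 differences changed by -3.03, -2.56 and 2.88, against the direction of the means. They are thus not differences of like size kept at all 3 stages. The stages went both ways for Gzma, which stood at 6.38 in rested Th1 and 5.94 in rested Th2 cells, and for B2m, at 10.60 in memory Th1 and 10.62 in memory Th2 cells. Of the B cell markers (2 measured) and the CD8 T and NK cell markers (2 measured), 0 were called by limma in any of the 12 comparisons. Adjusted over the list alone, 1 B cell marker was lower in either effector group than in naive cells and 2 were higher in memory than in rested Th2 cells. No list of T cell activation, apoptosis or stromal genes was called by camera in any comparison. By fry, apoptosis genes were higher in effector Th1 than in naive cells (adjusted p = 0.0491) and lower in rested than in effector Th1 (0.00222) and Th2 cells (0.0208). Also by fry, T cell activation genes were lower in rested than in effector Th1 cells and stromal genes lower in memory than in rested Th1 cells (adjusted p = 0.0339 for either).

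Tests of the interaction asked whether a step differed between the lineages. Such a difference is also the lineage difference after the step minus that before it. Gzma and Ifitm3 were already called between effector Th1 and Th2 cells, and Prkci between memory Th1 and Th2 cells. Their interaction calls are therefore not separate from those calls. The rest step differed for 5 reporters (174 at unadjusted p under 0.05; 12 with the replicate block, 398 with the shared pattern as a random block) and the memory step for 3 (343; 52 and 823). On the a arrays alone 2 were called for the rest step. For the memory step 0 were called by limma on the b arrays and with only the groups compared (250 and 232 at unadjusted p under 0.05). Gzma fell by 4.30 in Th2 cells at rest and had a change of -0.17 in Th1 cells, a difference of 4.13 ± 0.37 (SE, n = 3 per group, adjusted p = 4.18e-06). Ifitm3 fell by 5.43 in Th1 and by 2.40 in Th2 cells, and the difference of -3.03 ± 0.42 passed (adjusted p = 0.00178). From rested to memory cells Prkci rose by 2.05 in Th2 cells and had a change of -1.31 in Th1 cells, a difference of -3.36 ± 0.46 (adjusted p = 0.0029). The count for the rest step was 2 without effector Th1 1, effector Th1 3, effector Th2 1, effector Th2 2, rested Th2 1 or rested Th2 2, and 3 without rested Th1 3, effector Th2 3 or rested Th2 3. For the memory step it was 7 without rested Th1 2, 26 without rested Th1 3, 14 without rested Th2 1, 8 without memory Th2 2, and 1 without memory Th1 1, memory Th1 3, rested Th2 2, rested Th2 3 or memory Th2 3.

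**Figure D3:**
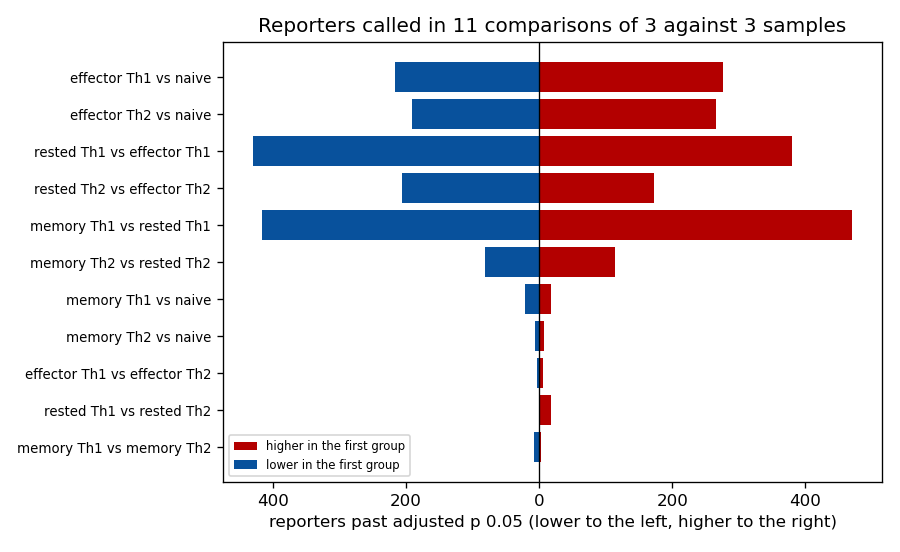
Bars give the number of reporters past adjusted p 0.05, higher in the first group to the right and lower to the left, for 11 comparisons of 3 against 3 samples by limma. Steps in culture and after transfer called 195 to 887 reporters, memory against naive cells 39 and 14, and Th1 against Th2 cells 9, 18 and 10. The steps set samples of different spot patterns against each other, while most samples in the other comparisons shared theirs.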

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

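The tests of the shared spot pattern, of the myeloid transcripts and of the count in the rest step, and the splits that exchange labels within pairs, were chosen only after those results were seen, while the counts over the other splits of the samples were planned before they were run.

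The change from effector to rested cells differed between lineages by the interaction test for 5 reporters. This contrast is also the lineage difference at rest minus that in effector cells. Gzma, Ifitm3, Myo6 and Prnp were already called between effector Th1 and Th2 cells, from the same effector samples. Their interaction calls are therefore not separate from those calls, nor evidence of a response particular to rest. Gzma fell in Th2 cells at rest and had a change of -0.17 in Th1 cells, a difference of 4.13 ± 0.37 (SE, n = 3 per group) that passed in each of the 12 fits without 1 sample (highest adjusted p = 3.92e-05). Ifitm3 fell in both lineages with a difference of -3.03 ± 0.42, which also passed in all 12 fits (highest adjusted p = 0.0111). The difference for Myo6 was 2.88 ± 0.53 (adjusted p = 0.0281), with changes of -0.91 in Th1 and -3.79 in Th2 cells, and it passed without rested Th1 2 but in none of the other 11 fits (adjusted p from 0.062 to 0.116). For Prnp it was -2.56 ± 0.46 (adjusted p = 0.0248), lost in 8 of 12 fits, those without effector Th1 1 or 3, rested Th1 2 or 3, effector Th2 1 or 2 and rested Th2 1 or 2 (adjusted p there from 0.0672 to 0.116). For 1 reporter unnamed here it was 1.91 ± 0.34 (adjusted p = 0.0248), kept only without effector Th1 2 and without rested Th1 3 (adjusted p from 0.0521 to 0.116 in the other 10 fits).

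The change from rested to memory cells differed between lineages for 3 reporters. Prkci and S100a9 among them were also called between memory Th1 and Th2 cells, from the same memory samples, so these calls are not separate from those. Prkci gave -3.36 ± 0.46 (SE, n = 3 per group) and passed in all 12 fits without 1 sample (highest adjusted p = 0.0187). S100a9 gave -2.64 ± 0.46 (adjusted p = 0.0255), with changes of -1.76 in Th1 and 0.87 in Th2 cells, and was lost in 5 of 12 fits, those without memory Th1 1 or 3, rested Th2 2 or 3 and memory Th2 3 (adjusted p there from 0.0738 to 0.138). Its group mean in memory Th1 cells was 0.44, against a median reporter of 3.13. Another reporter unnamed here gave -2.59 ± 0.44 (adjusted p = 0.0255), lost in 7 of 12 fits, those without rested Th1 1, memory Th1 1 or 3, rested Th2 2 or 3 and memory Th2 1 or 3 (adjusted p there from 0.055 to 0.138).

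The 6 samples of a comparison in groups of 3 make 10 splits, too few for a share under 0.05. In 9 of the 11 comparisons the real split was the only 1 of 10 with as many calls and the highest other split had 0 calls: 493 and 456 for effector Th1 and Th2 against naive cells, 810 and 378 for rested against effector Th1 and Th2 cells, 195 for memory against rested Th2 cells, 39 and 14 for memory Th1 and Th2 against naive cells, 9 for effector Th1 against Th2 and 18 for rested Th1 against Th2. Memory against rested Th1 cells had 887 calls in the real split and 4 in the highest other, or 3 among the splits that part 3 pairs of numbers. For memory Th1 against memory Th2 cells, with 10 calls, 5 of 10 splits called as many, the highest other 112. That split set memory Th1 1 with memory Th2 1 and 3 and so parted 1 pair of numbers, while the other splits that part 3 pairs, as the real one does, called 0 by limma, which points to a structure of the samples by number. With lineage labels redrawn freely within each stage, 3 of 100 splits called as many as the lineage mean (16; highest other 35), a share under 0.05. Most such splits leave some same-numbered pairs in 1 lineage, while the real split parts every pair. With labels exchanged only within pairs, every pair stayed parted. The real split was then the only 1 of 100 run, of 256 possible, to call as many, the highest other 10. As many calls as for the lineage mean were thus rare in that form, which does not exclude chance. The free splits cannot decide it, because they are unlike the real one, and the shares were not adjusted over the contrasts tried. As many calls as in the rest step (5) came from 8 of 100 free splits, highest other 19, and 6 of 32 within pairs, highest other 19. As many as in the memory step (3) came from 14 of 100 free splits, highest other 121, and 2 of 32 within pairs, highest other 8. Chance cannot be excluded for either step. The splits with 19 and with 121 calls, several times the real counts, point to a structure of the samples.

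Arrays of different groups shared 1 spot pattern in 13 pairs of samples. The same array hybridised again with another sample is argued against by the ratio of array a to array b, where new hybridisations would add noise of their own. That ratio was the same within 0.005 log2 at 100.0% of spots with an intensity of at least 3 in every such pair. The pairs were picked by this agreement, so the percentage restates the observation and is not a separate test. One array deposited under 2 labels is argued against by the log2 ratio between the samples of a pair, with an SD of at least 0.362. Values rebuilt as 1 spot pattern times 1 factor per reporter remain a candidate explanation, since both spots of a reporter gave the same ratio between the samples for 100.0% of reporters in every pair. No biological explanation was tested, and what made the pattern shared stays open.

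Myeloid and granulocyte transcripts stood higher in naive cells, with Lyz2 at 6.17, S100a9 at 5.30 and Fcer1g at 5.48 as group means. All 4 comparisons against naive cells kept the call of the myeloid list by camera after median centring. This cannot decide on scaling between arrays, because camera sets the list against other genes, and a shift common to an array hardly moves that contrast. One naive sample that stands apart is argued against, since the myeloid list kept its call in those 4 comparisons without any 1 naive sample (highest adjusted p = 0.0118 by camera). That test leaves out the granulocyte markers. Monocytes or granulocytes among the naive cells cannot be told apart from a difference within the T cells: 6 of 15 measured markers had their highest group mean in naive cells, between the 8 and the 2 set as bounds after the group means had been seen. The other markers included Csf3r at 7.17 in naive and 8.24 in rested Th1 cells and Ctsb at 5.46 and 5.51, 5 of the 15 lay above the median reporter (3.13) in every other group, and 1 is held by another list. The labels describe the naive cells as CD44-low, CD62L-high, CD45RB-high and CD25-negative, and whether that selection removed monocytes or granulocytes was not tested. A difference between naive and stimulated T cells was not tested on its own either.

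More reporters were called in the rest step of Th1 than of Th2 cells, 810 against 378, a ratio of 2.14. Scaling between arrays is argued against by the ratio of counts, which was 2.39 with median centring and 2.11 with cyclic loess. Unequal scatter of the samples may account for it: with array weights the counts were 867 and 985 (ratio 0.88), and with only the groups compared 570 and 506 (ratio 1.13), but the replicate block, which removes scatter shared by number, left most of the excess (1362 and 790, ratio 1.72). An earlier pair of tests used the median ratio of the Th1 to the Th2 change over the 378 reporters called in Th2 cells. That ratio was 1.04 (1.03 with cyclic loess), with a 95% bootstrap interval of 0.98 to 1.10. The bootstrap resampled reporters, so its interval leaves out the spread between samples. These tests met what both scaling and scatter predict. They were set aside as unfit because scaling hardly moved that ratio and choosing reporters by their Th2 call lowers it. The tests on counts were chosen after those values and the counts under array weights had been seen. The verdict against scaling thus rests on the second choice of test, and a larger response of Th1 cells stays open: the interaction, tested over 4992 reporters, passed for 5 (174 at unadjusted p under 0.05).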

How the results depend on the processing

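The pattern shared between samples as a random block, the naive and memory samples numbered 2 left out, and the list tests without each sample were tests chosen only after the data were seen. Of 453 results of named genes and called list members, all 453 kept their call with the replicate block, 451 with the series matrix, 451 with a larger offset, 449 with a trended and robust variance, 435 with 42 arrays, 432 with cyclic loess, 427 with array weights, 421 with the pattern as a block, 416 with median centring, 387 on the a arrays, 364 on the b arrays and 335 with only the groups compared, and 379 of 379 in the brighter 50% of reporters. With the samples numbered 2 left out 245 of 291 were kept, and without 1 sample 2359 of 2874. The only reversal was B2m in memory against rested Th1 cells, which fell by 0.67 and stood at 0.35 with median centring (adjusted p = 0.343; alternatives from 0.00196 to 0.343). Of 45 called list tests 42 held with median centring and 35 of 40 in the brighter 50%, 27 held without each sample in turn, and 17 held with an estimated correlation. Without a measured background the signal at which a dim reporter stops being informative is unknown, so low levels and the change of dim genes cannot be bounded. Where a value moved, the cause was not tested. Fits of only the groups compared or of 20 samples also had fewer samples behind them, and the effect of that was not tested either. A group left with 2 samples took its spread from all groups.

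With the replicate block, which follows the pairing of samples by number, the counts were 836 and 761 for effector Th1 and Th2 against naive cells, 1362 and 790 for rested against effector Th1 and Th2 cells, 1607 and 719 for memory against rested Th1 and Th2 cells, 298 and 70 for memory Th1 and Th2 against naive cells, 26, 118 and 20 for Th1 against Th2 effector, rested and memory cells, 37 for the lineage mean, 12 for the rest step and 52 for the memory step. The block kept the calls of all 453 results of named genes and called list members and raised many counts of called genes within lists. Apart from the list calls printed with it, it changed no other list call by camera.

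With 42 arrays and the sample as a random block (correlation 0.599) the counts that moved were 591 for rested against effector Th2, 313 for memory against rested Th2, 122 and 26 for memory Th1 and Th2 against naive, 20, 103 and 16 for Th1 against Th2 effector, rested and memory cells, 41 for the lineage mean, 8 for the rest step and 44 for the memory step. With the shared pattern as a random block (correlation 0.784) they were 1489 and 1187 for memory Th1 and Th2 against naive, 121, 1005 and 396 for Th1 against Th2 effector, rested and memory cells, 514 for the lineage mean, 398 for the rest step and 823 for the memory step. Array weights gave 769 and 810 for effector Th1 and Th2 against naive, 985 for rested against effector Th2, 547 for memory against rested Th1, 26, 37 and 5 for Th1 against Th2 effector, rested and memory cells and 13 for the rest step.

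On the a arrays alone the counts that moved were 18 and 8 for memory Th1 and Th2 against naive, 0 for rested Th1 against Th2 by limma (352 at unadjusted p under 0.05), 5 for memory Th1 against Th2, 7 for the lineage mean and 2 for the rest step. On the b arrays they were 576 and 127 for memory against rested Th1 and Th2, 21 and 6 for memory Th1 and Th2 against naive, 9 for rested Th1 against Th2, 10 for the lineage mean, 3 for the rest step and, by limma, 0 for the memory step (250 at unadjusted p under 0.05). With only the groups compared they were 182 and 46 for memory against rested Th1 and Th2, 8 and 4 for memory Th1 and Th2 against naive, and by limma 0 for rested Th1 against Th2, 0 for memory Th1 against Th2 and 0 for the memory step (388, 92 and 232 at unadjusted p under 0.05).

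Median centring gave 103 for memory against rested Th2, 8 for memory Th2 against naive, 7 for rested Th1 against Th2 and 10 for the memory step. Cyclic loess gave 59 and 8 for memory Th1 and Th2 against naive and 13 for the memory step. The brighter 50% gave 9 for memory Th2 against naive, 15 for effector Th1 against Th2 and 6 for the memory step. A larger offset gave 14 for effector Th1 against Th2, and a trended and robust variance gave 14 there and 5 for memory Th1 against Th2. Without the samples numbered 2 the counts were 427 for memory against rested Th2 and 1 for the memory step. The series matrix moved no count. Among lists, median centring added the proteasome in effector Th1 (adjusted p = 0.00539) and effector Th2 (0.00999) against naive cells and in memory Th1 against Th2 cells (0.00536), and ribosomal proteins in rested (0.000597) and memory (0.00997) Th1 against Th2 cells. None of these passed with an estimated correlation.

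Without 1 sample at a time the counts ran from 351 to 396 and from 312 to 368 for effector Th1 and Th2 against naive, 522 to 834 and 214 to 367 for rested against effector Th1 and Th2, 555 to 882 and 94 to 305 for memory against rested Th1 and Th2, and 14 to 94 and 6 to 33 for memory Th1 and Th2 against naive. They ran from 6 to 9, 0 to 43 and 4 to 17 for Th1 against Th2 effector, rested and memory cells, 11 to 23 for the lineage mean, 2 to 4 for the rest step and 1 to 26 for the memory step. Called list tests ran from 39 to 49.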

Other observations

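The genes below belong to lists fixed before the data were examined and were chosen for printing after their values had been seen. Effector samples of both lineages came from culture with antigen-presenting cells, and which cells carried their stromal transcripts was not tested. Some stromal markers stood higher in these samples than in naive ones. The fibronectin gene Fn1 rose by 2.03 ± 0.32 in effector Th1 and 2.00 ± 0.32 in effector Th2 cells (SE, n = 3 per group), and the PDGF receptor gene Pdgfrb by 1.92 ± 0.32 and 1.82 ± 0.32. These were the called members among 11 stromal markers (3 in Th1 and 2 in Th2 cells adjusted over the list alone). The list did not pass (adjusted p = 0.652 and 0.802), and its median change was -0.16 and -0.35 against a mean of 0.22 and 0.15. The co-stimulatory receptor gene Tnfrsf9 rose by 2.06 ± 0.34 and 2.19 ± 0.34, and the caspase gene Casp6 by 3.34 ± 0.38 and 2.57 ± 0.38. Chaperone genes went both ways in effector Th1 cells, where Hsp90b1 rose by 1.43 ± 0.20 and Dnaja1 fell by 1.31 ± 0.25 (2 of 15 rose and 1 fell, also adjusted over the list alone; list adjusted p = 0.655). The ribosomal protein gene Rpl10a fell by 1.52 ± 0.26 in effector Th1 and by 1.39 ± 0.26 in effector Th2 against naive cells, and rose by 1.29 ± 0.26 and 1.41 ± 0.26 at rest, where the same effector samples entered the comparison.

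In memory against rested Th1 cells 7 of 36 cell cycle genes rose and 1 fell, also adjusted over the list alone (7 and 2 with the replicate block), and the list did not pass (adjusted p = 0.279). Gmnn rose by 1.38 ± 0.23 and the Cdk-binding protein gene Cks2 by 1.51 ± 0.31 (SE, n = 3 per group). The cytochrome c gene Cycs rose by 2.07 ± 0.24 in memory against rested Th1 cells, and Cd1d1 rose by 1.55 ± 0.31. Group means of Gzma were 6.52 in naive, 6.54 in effector Th1 and 10.24 in effector Th2 cells, and 6.38 in rested Th1 and 5.94 in rested Th2 cells, while Gzmb stood at 2.48 in naive and at 6.08 and 6.80 in effector Th1 and Th2 cells.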
